A study of Homo sapiens with 8 samples.

How the data were processed

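Single cells dissociated from human pituitary tissue were measured by droplet RNA sequencing from the 3' end in 8 libraries of 5 donors. The labels place 2 libraries in Cushing's disease (CD) adenoma, 1 in growth hormone (GH) adenoma, 1 in non-functioning pituitary adenoma (NFPA) and 3 in adjacent normal gland. The eighth library holds a CD adenoma together with normal gland of 1 donor, so it entered no comparison of groups and is given as values. Numbers in the sample titles pair CD adenoma 2 with normal gland 2, CD adenoma 3 with normal gland 3 and GH adenoma 4 with normal gland 4, each pair from the same donor.

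The deposited matrices hold raw UMI counts, 1 count per unique molecule of a gene in a cell barcode, made with Cell Ranger 2.1.1 against GRCh38 per the submitters' processing notes. The version is uncertain, since the feature tables have 3 columns, the layout of later versions. The barcodes of NFPA carry 2 suffixes, as joined channels do: 71 of its kept cells have the first, among them 33 of its 48 T-cell-like cells and no gonadotroph-like cell, and 8485 the second. It was treated as 1 library, also when doublets were scored. The authors had already called cells, since no barcode holds only a few UMIs. The files list 33538 genes with Ensembl identifiers, of which 33456 matched GENCODE release 29, the source of the positions given on GRCh38. A total of 102 genes (the Y chromosome, XIST and TSIX) were left out of the summed counts and the tests, because donors differ in them, which left 33436. They stayed in the cell filters, the doublet scores and the clustering. The 48 genes whose symbol is held by more than 1 identifier were kept apart by identifier. Use of the strand in counting was not given in the sources used here.

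Cells were kept with at least 500 UMIs, at least 200 genes and at most 20% of UMIs from mitochondrial genes. Doublets were scored per library with scrublet as run by scanpy 1.11.5 (anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, pandas 2.3.3, Python 3.11.15). It called 128 of 35859 cells (0.357%), a share so low that the caller cannot be said to have worked, and 35731 cells remained. All libraries were clustered together without batch integration: 2000 variable genes, 30 principal components, 15 neighbours and leiden at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, seed 0). Of 33 clusters, 24 with 30055 cells were named from 85 marker genes of 18 classes fixed before the data were examined. A marker counted for a cluster at 15% or more of its highest cluster's level and in at least 5% of its cells. A name needed 3 markers, a 2-fold lead in marker level over any class of another compartment, and fewer than 2 of its 10 leading genes shared with a named cluster of another compartment. A cluster led by more markers of another class, or by another class's hormone, stayed unnamed, as did shallow clusters led by no marker of the class. Leading genes were ranked by fold over the other clusters with a pseudocount of 5 counts-per-million (CPM) among genes in at least 10% of the cluster. These naming thresholds were set after the clusters had been seen. Clusters in which no class had that lead stayed unnamed, and their share is given per library. Some named clusters met markers of another compartment as well: the neutrophil-like cluster (436 cells) met POMC, TBX19 and PCSK1, a corticotroph-like cluster of 264 cells HBB, HBA1 and HBA2, and the erythroid-like cluster (117 cells) all 5 T-cell markers. Thyrotroph, pituicyte, pericyte, B-cell, plasma-cell and mast-cell names went to no cluster.

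Counts were summed per library and class, and CPM is scaled to the total of the kept genes of that class in that library. Groups were compared with edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr, limma 3.58.1, R 4.3.3), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. A library entered a class with at least 20 cells. Corticotroph-like cells were compared between CD adenoma and normal gland, as were all cells of a library. Non-endocrine classes were compared between all adenoma libraries and normal gland where at least 3 adenoma libraries and 2 normal libraries had enough cells. Only 1 normal library had enough corticotroph-like cells, so a second fit without the minimum, with all 3 normal libraries, was added after seeing the data. Shares of cells were compared with two-sided exact permutation tests over all 10 splits of 2 against 3 libraries, for which the smallest possible p is 0.2. A total of 20 gene lists, fixed before the data were examined, were tested with camera (preset correlation 0.01, and also with an estimated correlation) and fry, each list needing 3 tested members. The lists cover hormone processing, glucocorticoid response, the BCL2 family, EGFR signalling, CRH and cAMP signalling, proliferation, cell cycle inhibitors, G1 cyclins, immediate early genes, the unfolded protein response, somatostatin and dopamine receptors, pituitary lineage factors, mitochondrial transcripts, nuclear oxidative phosphorylation, ribosomal proteins, antigen presentation, interferon response, hypoxia and glycolysis, other pituitary hormones, and blood and vessel markers. GH adenoma and NFPA have 1 library each, so their values and folds carry no test, and each list's median fold (pseudocount 1 CPM) was set against 10000 random lists of the same size. Members of the random lists were drawn independently from genes of like mean expression. Genes of a real list can move together, so an extreme percentile can arise between any 2 libraries and is no test.

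Genes are named by a rule fixed before the data were examined. It takes the 10 genes with the smallest adjusted p in each direction among those called, 21 genes of corticotroph biology in every case, and called list members. For folds with no test it takes the 10 largest in each direction among genes with at least 50 CPM on one side and at least 10 counts, in the same direction against every normal library. Genes with clone names, ribosomal, mitochondrial and immune receptor genes were excluded from the rule. Genes named outside it are marked as chosen after their values were seen. A fold against 0 counts was taken against a floor of 3 counts per library. Intervals are 95% (exact Clopper-Pearson for shares, exact Poisson for CPM) and cover counting error only.

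The edgeR and DESeq2 (1.42.0) tests were tested on simulated data with the same library sizes and numbers. Each comparison was 1 draw in which all genes had the same dispersion, the spread between libraries. Genes of the data differ in spread, so the counts of false calls below set no rate for the data. With 2 libraries against 1, edgeR recovered 0% of genes changed 8-fold and DESeq2 11.1%, and 5 of its 14 calls were false. For all cells 29 of 90 DESeq2 calls were false and 0 of 30 with edgeR. The fit against all 3 normal libraries recovered 12.3% at 8-fold with edgeR, where 2 of 10 calls were false. In the simulated fit of 2 against 1, a list raised 2-fold passed camera with the preset correlation, which also called 1 unchanged list. It had an adjusted p of 0.9938 with an estimated correlation and 0.7996 with fry, so neither found it. This was 1 simulated draw of 1 raised list, with genes drawn independently. In the data the estimated correlation was 0.35 for lineage factors and 1 for mitochondrial transcripts. The draw therefore sets no rate of missed or falsely called lists. The non-endocrine fits recovered between 55.4% and 76.9% of genes changed 4-fold with edgeR. False calls with edgeR were 11 of 132 in the endothelial fit and 5 of 118 in the stem-like fit. Alternatives were DESeq2, size factors by median of ratios in the same edgeR fit, no filter on low counts, the replicate block (the donor number as a term of the model), leaving out each replicate in turn, leiden resolutions 0.5 and 2, at most 10% mitochondrial UMIs, doublets kept (with all cells clustered and named anew), endocrine classes alone, cells thinned to 1000 UMIs, and corticotroph-like cells in which no other hormone exceeds 1% of UMIs. With the replicate block, a library whose donor has no library in the other group adds nothing to the difference between groups. Alternatives added after seeing the data were removal of the 1352 cells with the highest doublet scores (0.8% per 1000 cells of a library), the fit without a minimum of cells, the larger cluster of stem-like cells alone, and the lactotroph-like class together with the unnamed clusters that have PRL among their 10 leading genes. The folds of GH adenoma 4 against the normal gland of the same donor were also added then, and so was a clustering of all cells without the 4 genes called in stem-like cells and 5 close relatives of SAA1 and AKR1C1.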

Results

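Gene expression was measured in single cells of human pituitary adenomas and of the gland beside them. Corticotroph adenomas of Cushing's disease secrete ACTH, which is made from the precursor POMC. GH adenomas arise from growth hormone cells, and NFPA secretes no hormone in clinical excess. After quality control 35731 cells remained. CD adenomas 2 and 3 gave 4773 and 2691 cells, with 21668395 and 23129274 UMIs over all barcodes and medians of 3079 and 4423 UMIs per kept cell. Normal glands 2, 3 and 4 gave 5165, 4477 and 3051 cells, from 18893750, 32451690 and 9200021 UMIs, with medians of 2053, 5293 and 1756. GH adenoma 4 gave 4001 cells from 10884522 UMIs (median 1928) and NFPA 5 gave 8556 cells from 28072843 UMIs (median 2980). The library of CD adenoma plus normal gland gave 3017 cells of 8483 barcodes from 16392223 UMIs (median 2339).

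The first question was which cells each tissue held. The cells held by the CD adenomas differed widely between the 2 donors. Corticotroph-like cells, which express POMC and its activator TBX19, made up 91.1% of CD adenoma 2 (95% interval 90.3 to 91.9%) but 2.75% of CD adenoma 3 (2.17 to 3.44%). They made up 2.41%, 0.174% and 0.0656% of normal glands 3, 2 and 4, and 34.6% of the library of adenoma plus normal gland. Somatotroph-like cells, the source of growth hormone, made up 0.105% and 14.98% of the CD adenomas and 37.6%, 39.6% and 9.93% of normal glands 2, 3 and 4. Gonadotroph-like cells made up 83.5% of NFPA 5, and 0 of its 8556 cells were corticotroph-like, with an upper 95% limit of 0.0431%. The NFPA share depended on the clusters: it was 62.7% at leiden resolution 2 and 0.199% at resolution 0.5, where 96.9% of the library stayed unnamed.

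In CD adenomas the mean corticotroph-like share was 46.9% ± 62.5 (SD, n = 2) against 0.884% ± 1.33 (n = 3) in normal gland. The difference of 46.1 percentage points had a two-sided exact permutation p of 0.2, the smallest that 2 against 3 libraries allow, and higher shares in 2 of 2 adenomas. Within donors it was 91.0 points in replicate 2 and 0.338 points in replicate 3, so CD adenoma 2 alone carried it, and without that library the difference was 1.87 points. Somatotroph-like cells averaged 7.54% ± 10.5 against 29.04% ± 16.6 (exact permutation p = 0.4). Lactotroph-like cells, named from PRL, DRD2 and ESR1, averaged 2.47% ± 3.50 against 11.2% ± 8.53 (exact permutation p = 0.4). Their cluster also met the somatotroph markers GHRHR, DLK1 and POU1F1, and PRL was not among its 10 leading genes. Whether this class holds the prolactin cells of the gland was not tested. Within donors the lactotroph-like share differed by -8.13 points in replicate 2 and 0.363 points in replicate 3, and the somatotroph-like share by -37.5 and -24.6 points. The 3 unnamed clusters with PRL among their leading genes, set beside that class after the data were seen, held 0.0419% and 24.1% of CD adenomas 2 and 3 and 8.96%, 23.1% and 5.83% of normal glands 2, 3 and 4. Together with them the mean was 14.55% ± 20.5 against 23.8% ± 5.85 (exact permutation p = 0.8). Gonadotroph-like cells averaged 2.84% against 5.35%, endothelial-like cells 1.46% against 6.57%, fibroblast-like cells 2.04% against 5.68% and stem or folliculostellate-like cells 2.15% against 4.70%. Macrophage- or monocyte-like cells averaged 3.92% against 6.63% and T-cell-like cells 11.6% against 7.29%. Within donors the difference was -7.15 points in replicate 2 but 1.31 points in replicate 3 for endothelial-like cells, -2.98 and 2.46 points for fibroblast-like, -8.43 and 1.71 points for stem or folliculostellate-like and -6.24 and 3.91 points for macrophage- or monocyte-like cells. For gonadotroph-like cells it was -7.24 points in replicate 2 and -1.86 points in replicate 3. The T-cell-like share was 21.3% in CD adenoma 3 and 1.89% in CD adenoma 2, with a difference of means of 4.32 points. Within donors it was higher in the adenoma by 0.743 and 12.2 points in replicates 2 and 3, and by 6.21 points in the GH adenoma of replicate 4. An unnamed cluster, chosen after its values were seen, met CD3D, CD3E, CD2 and TRAC beside NK-cell markers. It held 72 cells of CD adenoma 2 and 198 of normal gland 2, where the T-cell-like class held 90 and 59. Counted with that class it would turn the direction in replicate 2, but not in replicates 3 and 4. Unnamed clusters held 2.56% and 30.7% of the CD adenomas, 17.3%, 27.6% and 15.7% of normal glands 2, 3 and 4, 11% of GH adenoma 4, 12.5% of NFPA 5 and 20.3% of the library of adenoma plus normal gland.

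**Figure D1:**
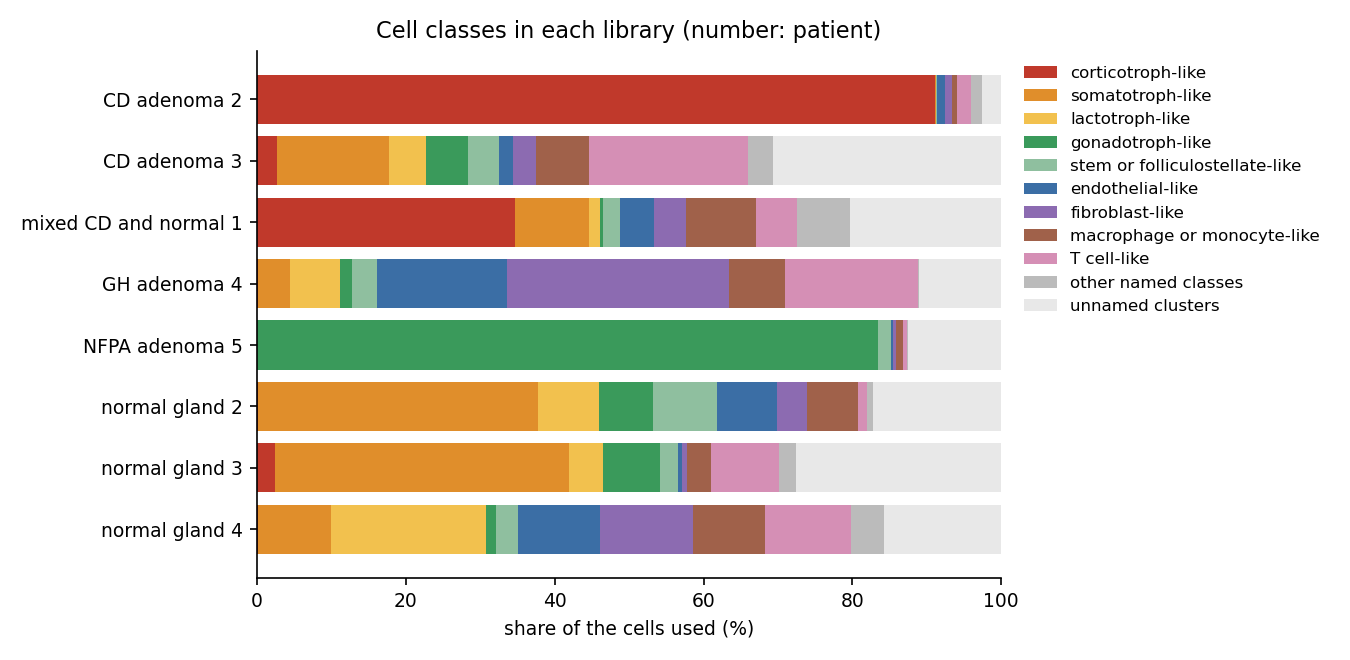
Share of cells (percent, horizontal axis) in each class, 1 stacked bar per library; the number after each library is its donor and no error is drawn. The corticotroph-like class fills 91.1% of CD adenoma 2 and 2.75% of CD adenoma 3, and the gonadotroph-like class fills 83.5% of NFPA 5.

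The central comparison asked what corticotroph-like cells of CD adenomas express differently from those of normal gland. The hormone precursor itself was at a like level in the CD adenomas and normal gland 3. POMC (chromosome 2, 25160853 to 25168903) took 168000 and 146400 CPM in CD adenomas 2 and 3 and 166800 CPM in normal gland 3, the 1 normal library with enough cells. TBX19, the factor that defines the lineage, stood at 348.5, 342.5 and 366.5 CPM. PCSK1 (chromosome 5, 96390415 to 96434143), the convertase that cuts POMC into ACTH, stood at 97.6 and 247 CPM against 12.9 CPM. PMAIP1 (chromosome 18, 59899948 to 59904306), a pro-apoptotic member of the BCL2 family, stood at 613.6 and 505.1 CPM against 215.0 CPM. The cells numbered 4350 in CD adenoma 2, 74 in CD adenoma 3 and 108 in normal gland 3, with 20133767, 1555980 and 1009452 UMIs. Of the 74 cells of CD adenoma 3, 53 lie in a cluster that holds 92 of the 108 cells of normal gland 3. Whether the 74 are adenoma cells or normal corticotrophs of the same piece of tissue was not tested. In corticotroph-like cells with no other hormone over 1%, PMAIP1 stood at 248.8 CPM in normal gland 3. In 7 such cells of normal gland 2 it stood at 521.5 CPM (250.1 to 959). In 2 of normal gland 4 it stood at 813 CPM (444.5 to 1364). The intervals of normal glands 2 and 4 hold the values of both CD adenomas in such cells. The higher PMAIP1 was thus a difference from normal gland 3, not shown against normal glands 2 and 4. POMC in such cells stood at 168000 and 216300 CPM in CD adenomas 2 and 3 and at 200300 CPM in normal gland 3. It was lower in the few such cells of normal glands 2 and 4, at 83120 and 124600 CPM. The like level of POMC was thus shown against normal gland 3 alone.

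With 2 libraries against 1, edgeR called 0 of 10270 genes, with 285 at an unadjusted p under 0.05 and a smallest adjusted p of 0.998. DESeq2, with 5 of 14 calls false in simulated data of this design, called 19 (5 higher, 14 lower in the adenomas), and edgeR on cells thinned to 1000 UMIs called 21 of 1839. The log2 difference was -0.02 (SE 0.96) for POMC, -0.02 (SE 0.56) for TBX19, 3.80 (SE 0.92) for PCSK1 and 1.45 (SE 0.61) for PMAIP1. It was 0.46 (SE 0.67) for BCL2L1 and 0.20 (SE 0.52) for MCL1, which oppose cell death. NR3C1, the glucocorticoid receptor, differed by 0.21 (SE 0.55), and FKBP5, which it induces, by -0.63 (SE 0.58). EGFR differed by -1.74 (SE 1.52) and USP8, which removes ubiquitin from that receptor, by 0.08 (SE 0.52). The dopamine receptor DRD2 differed by 0.48 (SE 1.78). The cyclin CCND1 differed by -1.33 (SE 2.18), with 0.497 and 141 CPM in the CD adenomas against 182 CPM. The inhibitors CDKN1A and CDKN1B differed by -0.49 (SE 0.74) and -1.003 (SE 1.54), and the division marker MKI67 by -4.27 (SE 1.22), with an adjusted p (edgeR) of 0.9997 for each gene of this group. The hormone receptors CRHR1 and AVPR1B, the somatostatin receptors SSTR2 and SSTR5, BCL2 and CCNE1 had counts too low to test. AVPR1B, which binds vasopressin, stood at 1.34 and 3.86 CPM against 5.94 CPM. CRHR1 stood at 0.546 and 0 CPM against 0 CPM.

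**Figure D2:**
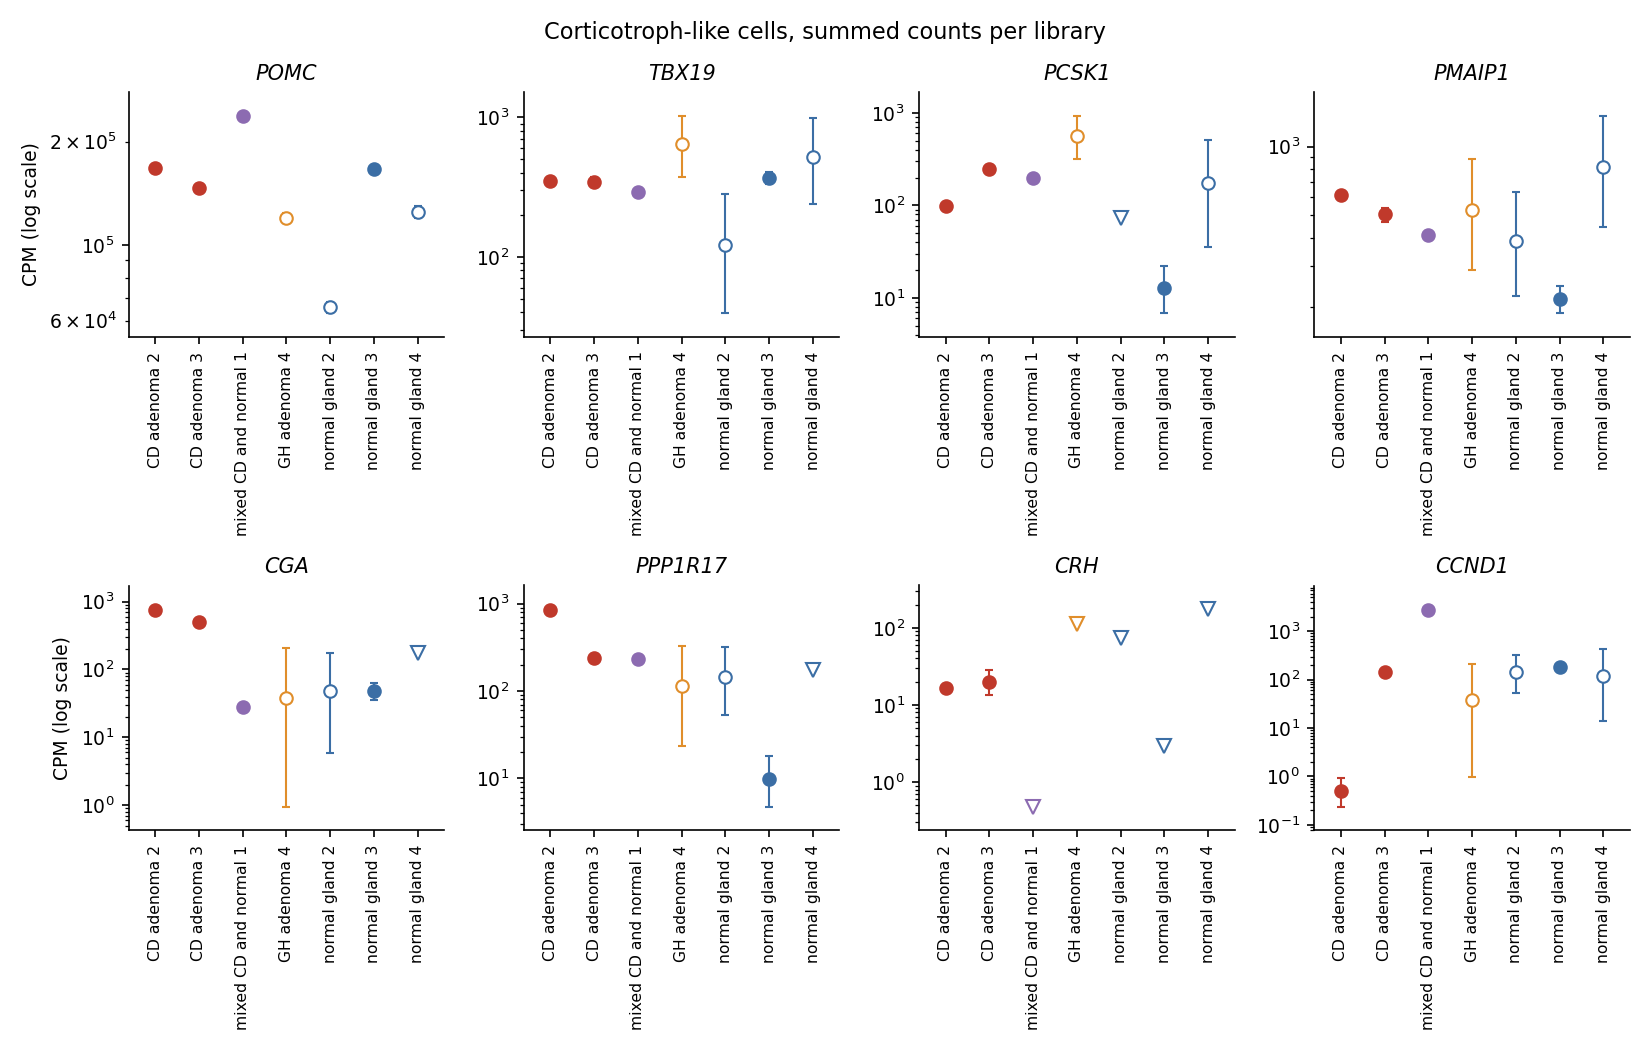
Expression of 8 genes in corticotroph-like cells, 1 point per library, in counts-per-million (CPM, log scale) with exact Poisson 95% intervals; filled points have at least 20 cells, hollow circles fewer, and open triangles mark a count of 0 drawn at the floor of 3 counts. POMC sits between 65600 and 237900 CPM in the CD and normal libraries and the library of adenoma plus normal gland, which holds the highest value. PCSK1 sits at 97.6 and 247 CPM in the CD adenomas against 12.9 CPM in normal gland 3, and CCND1 at 2811 CPM in the library of adenoma plus normal gland.

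Against normal gland 3, folds of single genes were larger, with no test. In CD adenoma 3, whose donor also gave that gland, PPP1R17, an inhibitor of protein phosphatases, was 24.4-fold higher, SEZ6L 23.0-fold, C14orf180 20.4-fold, TGFBR3L 20.3-fold and PCSK1 19.2-fold. DKK4, a WNT antagonist, was at least 27.5-fold and LCN1 at least 20.5-fold higher. FXYD5 was 63.6-fold higher against 1 count, with a pooled interval from 11.2, PART1 64.2-fold against 1 count (from 11.3) and PAPPA2 25.5-fold against 3 counts (from 8.52). FXYD5 stood at 50.5 and 63.0 CPM in corticotroph-like cells of CD adenomas 2 and 3, and at 139 and 51.9 CPM in all their other cells. It was thus not particular to corticotroph-like cells there. Other cells of normal gland 3 held 15.7 CPM. The kallikrein KLK11 was 87.4-fold lower and KLK12 385-fold on 2 counts, and the protease inhibitor SLPI 80.8-fold. The metallothioneins MT2A and MT1X were 23.9-fold and 21.0-fold lower, MT1G 60.1-fold on 3 counts and MT3 40.9-fold on 2 counts. RRAD and PCP4 were 32.0-fold and 23.9-fold lower. In CD adenoma 2, PPP1R17 was 86.0-fold, SPP1 40.3-fold, SEZ6L 38.8-fold, PCSK1 7.58-fold and PMAIP1 2.86-fold higher, and STXBP6 and CYP3A4 at least 102-fold and 42.1-fold. GSDMD was 137-fold higher against 2 counts (from 37.8), COX6A2 83.6-fold against 1 count (from 14.99), TMEM176B 70.4-fold against 1 count (from 12.6), FXYD5 50.9-fold against 1 count (from 9.12) and XRRA1 35.5-fold against 2 counts (from 9.80). SLPI, KLK11 and ALDH1A1 were 1493-fold, 484-fold and 1127-fold lower in CD adenoma 2, PCP4 and CD72 618-fold and 445-fold on 3 counts each, and RSPO2 1037-fold on 2 counts. The other-lineage genes PRL and GH1 were 8233-fold and 1699-fold lower, and DLK1 and POU1F1 6602-fold and 1616-fold on 1 count each. PRL took 191900 CPM of the corticotroph-like cells of CD adenoma 3, 33530 CPM in normal gland 3 and 4.07 CPM in CD adenoma 2, beside medians of 15640, 8298 and 3342 UMIs per corticotroph-like cell. STXBP6, PPP1R17 and GAL lead the cluster that holds 4242 cells of CD adenoma 2, and GAL, KLK12, KLK11, C14orf180 and MT1X lead the cluster that holds 92 of the 108 cells of normal gland 3 and 53 of the 74 of CD adenoma 3. Part of the differences of CD adenoma 2 from normal gland 3 thus defined the clusters.

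Set against all 3 normal glands (9, 108 and 2 cells), a comparison added after seeing the data, 28 of 8064 genes were called by edgeR, 15 higher and 13 lower in the CD adenomas. CGA (chromosome 6, 87085498 to 87095406), the alpha subunit shared by the glycoprotein hormones, rose by 4.17 on the log2 scale (SE 0.81, adjusted p = 0.000459), with 761.5 and 503.2 CPM against 48.6, 48.5 and 0 CPM. In cells with no other hormone over 1%, CGA stood at 591.7 and 25.0 CPM against 7.15 CPM in normal gland 3 (log2 4.77, adjusted p = 0.0143), so its level in CD adenoma 3 came mostly from cells that this limit, which reads CGA too, left out. PCSK1 rose by 3.33 (SE 0.82, adjusted p = 0.0175), although the 3 counts in normal gland 4 made 174 CPM there, between the CD adenomas. TMEM176A and TMEM176B, membrane proteins whose genes overlap on opposite strands, rose with adjusted p of 0.000366 and 0.00322. TMEM176A stood at 66.4 and 26.4 CPM in the adenomas and at 0 counts in the normal glands, and TMEM176B at 69.7 and 48.2 CPM against 24.3, 0.991 and 0 CPM. The 0 counts of TMEM176A allow up to 89.6, 3.65 and 214 CPM in normal glands 2, 3 and 4. In the library of adenoma plus normal gland, 1045 corticotroph-like cells held 2.08 CPM of TMEM176A (13 counts). PPP1R17 (adjusted p = 0.00058, log2 4.34), SPP1 (adjusted p = 0.000459, log2 4.41), which encodes osteopontin, FXYD5 (0.00397, log2 4.85), C14orf180 (0.00631, log2 3.94), SEZ6L (0.0126, log2 3.77) and FAM3B (0.0157, log2 5.24) rose in 2 of 2 adenomas relative to the normal mean. PPP1R17 stood at 852 and 242 CPM in the adenomas. In normal glands 2, 3 and 4 it stood at 146 CPM (6 counts, 53.5 to 317), 9.91 CPM and 0 counts (up to 214 CPM). All other cells of the CD adenomas held FXYD5 too, at 139 and 51.9 CPM. Those of normal glands 2, 3 and 4 held 18.9, 15.7 and 32.3 CPM. SAA1, an acute-phase protein, passed (adjusted p = 0.00596) with 90.8 CPM in CD adenoma 2 and 0 CPM in CD adenoma 3. SLPI fell by 6.83 (SE 0.95, adjusted p = 4.33e-09), RSPO2, a WNT agonist, by 5.15 (adjusted p = 5.03e-06), KLK12 by 3.49 (0.0018), SPARCL1 by 3.47 (0.00296) and OPCML by 6.90 (0.00596). KLK12 stood at 32.6 and 1.28 CPM against 494 CPM in normal gland 3 and 0 counts in normal glands 2 and 4, whose few cells allow up to 89.6 and 214 CPM, so its fall rested on 1 gland. SPARCL1 stood at 14.5 and 25.1 CPM against 121.5, 496 and 0 CPM, and OPCML at 0.149 and 0 CPM against 0, 17.8 and 116 CPM. CCNB1, the mitotic cyclin, fell by 3.16 (adjusted p = 0.0126), LAIR2 by 6.59 (0.0157), FGFR3 by 3.23 (0.0166), HPN by 2.74 (0.0271) and NCAM2 by 3.54 (0.0285), each with 2 of 2 adenomas below the normal mean. POMC (log2 0.89, SE 2.19), TBX19 and PMAIP1 were not called. With the replicate block 17 genes were called, from the pairs of donors 2 and 3 alone, since normal gland 4 has no CD adenoma of its donor. With DESeq2 2 genes were called, and in cells with no other hormone over 1% 17. The count was 0 without normal gland 3, 1 without normal gland 4 and 23 without normal gland 2, so it rested on normal glands 3 and 4. Leaving out a CD adenoma leaves 1 adenoma library, so such a fit cannot show the spread between adenomas.

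Gene lists asked whether pathways moved together in these cells between the CD adenomas and normal gland 3, and 9 of 19 testable lists passed camera with its preset correlation, 2 higher and 7 lower. None of the 9 passed with an estimated correlation or with fry, where 0 lists were called. In 1 simulated draw of this design, with genes drawn independently, a list raised 2-fold did not pass these either (adjusted p = 0.9938 and 0.7996). The preset correlation called 1 unchanged list there. The normal side was 1 library, 108 cells of normal gland 3, so the differences below are from that gland and not from normal gland in general. Proliferation genes were lower (adjusted p = 1.44e-07; adjusted p = 0.635 with an estimated correlation), with 10 of 12 tested members below 0 and 4 of them (MKI67, CCNB1, CCNB2 and BIRC5) called when adjusted over the list alone. CCNB1 stood at 5.36 and 4.50 CPM against 71.3 CPM. Glucocorticoid response genes were lower (adjusted p = 0.000558; adjusted p = 0.635 with an estimated correlation), 9 of 12 below 0, and 2 were called adjusted over the list alone, the metallothionein MT1X (298 and 154 CPM against 3240 CPM) and the kinase SGK1 (7.003 and 8.36 CPM against 37.6 CPM). Their median stood at -1.41 in CD adenoma 2 (percentile 0 of random lists) and -0.446 in CD adenoma 3 (percentile 10.1). Pituitary lineage factors were lower (adjusted p = 1.92e-09; adjusted p = 0.635 with an estimated correlation), 8 of 11 below 0, SOX4 among them at 8.99 and 18.0 CPM against 87.2 CPM. The difference of that list lay in CD adenoma 2 (median log2 -1.64 against normal gland 3, percentile 0 of random lists), while CD adenoma 3 stood at -0.142 (percentile 42.8). RNA of other hormones differed there too: the other pituitary hormones stood at -10.51 (percentile 0) in CD adenoma 2 and at 2.516 (percentile 100) in CD adenoma 3. Interferon response genes (5.59e-06, 6 of 9 below 0), cell cycle inhibitors (0.000196, 11 of 14 below 0) and G1 cyclins (0.000558, 6 of 6 below 0) were lower, each with an adjusted p = 0.635 with an estimated correlation. Ribosomal protein genes were lower (adjusted p = 0.0328; adjusted p = 0.735 with an estimated correlation), 16 of 18 below 0. Mitochondrial transcripts were higher (adjusted p = 0.00409; adjusted p = 0.763 with an estimated correlation), all 13 of 13 above 0. CD adenoma 2 alone carried it, with 13 of 13 above 0 against normal gland 3 (median 1.46), while CD adenoma 3 had 8 of 13 below 0 (median -0.255). Over all kept cells the median share of mitochondrial UMIs was 13.5% in CD adenoma 2, 4.25% in CD adenoma 3 and 5.12% in normal gland 3. Antigen presentation genes were higher (adjusted p = 0.0328; adjusted p = 0.649 with an estimated correlation), 8 of 11 above 0, with HLA-C higher and HLA-E lower (17.1 and 19.3 CPM against 141 CPM) when adjusted over the list alone. In CD adenoma 2 that list had 8 members above 0 and 8 below, and in CD adenoma 3 7 of 10 above 0.

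The other lists did not pass. Hormone processing and granule genes had 9 of 16 members above 0 (adjusted p = 0.258, median log2 0.18), the BCL2 family 7 of 14 (0.611, median 0.06) and EGFR signalling 1 of 6 (0.323, median -0.23). CRH, vasopressin and cAMP signalling had 11 of 14 above 0 (adjusted p = 0.0775, median 0.34), immediate early genes 5 of 18 (0.893, median -0.11) and the unfolded protein response 11 of 17 (0.289, median 0.12). Nuclear oxidative phosphorylation had 6 of 18 above 0 (adjusted p = 0.137, median -0.14) and hypoxia and glycolysis 7 of 12 (0.611, median 0.05). The other pituitary hormones had 3 of 4 above 0 (adjusted p = 0.226, median 2.67), with CGA called higher adjusted over the list alone. Blood and vessel markers had a test direction of lower (adjusted p = 0.159) although their median was 1.26. Of the somatostatin and dopamine receptors 1 of 6 could be tested, too few for a list. Against all 3 normal glands, added after seeing the data, 9 lists passed with the preset correlation, 4 with the replicate block, 0 with an estimated correlation and 0 with fry. They were partly other lists. Proliferation, lineage factors, interferon response, G1 cyclins and antigen presentation passed again, 5 of the 9. Glucocorticoid response (adjusted p = 0.381), cell cycle inhibitors (0.0703), mitochondrial transcripts (0.271) and ribosomal proteins (0.0703, with the direction turned to higher) did not. Hormone processing, CRH, vasopressin and cAMP signalling, the unfolded protein response and blood and vessel markers passed only there, the last 3 with an adjusted p of 0.0331 each. The count was 0 without normal gland 3 and 5 without CD adenoma 2. There hormone processing genes were higher (adjusted p = 0.0115; adjusted p = 0.471 with an estimated correlation), 12 of 16 above 0. Against normal gland 3 alone the adenomas went opposite ways in that list, with 12 of 16 below 0 in CD adenoma 2 (median -0.257, percentile 10.35 of random lists) and 11 of 16 above 0 in CD adenoma 3 (0.466, percentile 99.99).

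Taking all cells of a library together asked what a tissue as a whole expressed. POMC took 164700 CPM in CD adenoma 2 and 11620 CPM in CD adenoma 3, against 281, 5792 and 257 CPM in normal glands 2, 3 and 4, 150200 CPM in the library of adenoma plus normal gland, 369 CPM in GH adenoma 4 and 3.85 CPM in NFPA 5. PMAIP1 stood at 603 and 64.2 CPM against 16.2, 15.96 and 50.5 CPM, and PCSK1 at 96.1 and 22.8 CPM against 2.56, 7.86 and 15.1 CPM. GH1 stood at 5.77 and 28630 CPM against 29630, 56830 and 3147 CPM. With edgeR 0 of 17107 genes were called (488 at an unadjusted p under 0.05), with DESeq2 41 (39 higher, 2 lower; 29 of 90 calls were false in simulated data), and with the replicate block 0. Without CD adenoma 3 edgeR called 388 genes, 191 higher and 197 lower. The log2 difference was 5.58 (SE 2.16) for POMC, 4.70 (SE 1.15) for TBX19, 3.30 (SE 0.84) for PCSK1 and 4.15 (SE 0.99) for PMAIP1, each higher in 2 of 2 adenomas than the normal mean with an adjusted p of 0.926.

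Cells outside the hormone lineages could be compared across all adenoma types. In endothelial-like cells AQP1 (chromosome 7, 30911694 to 30925516), a water channel of vessel walls, was higher in all 4 adenoma libraries, at 578, 477, 101 and 465 CPM in CD adenomas 2 and 3, GH adenoma 4 and NFPA 5, against 25.1, 0 and 23.3 CPM in normal glands 2, 3 and 4. MEG3 (chromosome 14, 100779410 to 100861031), a long non-coding RNA, was lower, at 62.0, 0, 46.7 and 21.1 CPM against 725, 755 and 340 CPM. The cells numbered 47, 52, 696 and 29 in the adenomas and 420, 28 and 334 in the normal glands. edgeR called 2 of 3515 genes: AQP1 rose by 4.01 on the log2 scale (SE 0.67, adjusted p = 0.0408, 4 of 4 adenoma libraries above all normal libraries) and MEG3 fell by 4.33 (SE 0.65, adjusted p = 0.0253, 4 of 4 below all). RNA of hormone cells lay in these cells as well: PRL stood at 10230, 30080 and 6574 CPM in the normal glands against 0, 1499, 1341 and 21.1 CPM in the adenomas, and POMC at 10370 CPM in CD adenoma 2. Signs of RNA quality and dissociation moved between the same groups, with no test: mitochondrial transcripts had 13 of 13 below 0 in the adenomas (median log2 -0.703) and immediate early genes 17 of 18 (-0.724). With the replicate block, which compares the groups within 3 donor pairs alone, 49 genes were called (24 higher, 25 lower). NFPA 5 adds nothing to that difference. With DESeq2 19 genes were called (18 higher, 1 lower). Neither gene was called without CD adenoma 2, normal gland 2 or NFPA 5 (0 genes), 1 gene, MEG3, was called without CD adenoma 3, normal gland 3 or normal gland 4, and 37 without GH adenoma 4. With doublets kept, or at most 10% mitochondrial UMIs, 0 genes were called.

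Stem or folliculostellate-like cells, the SOX2-bearing support and progenitor cells of the gland, held 4 genes higher in the adenoma libraries and 0 lower among 7139 tested with edgeR. RARRES1, a retinoid-responsive gene, stood at 1081, 838 and 336 CPM in CD adenoma 3, GH adenoma 4 and NFPA 5 against 13.0, 12.5 and 23.4 CPM in normal glands 2, 3 and 4 (log2 5.51, SE 0.60, adjusted p = 0.00586). CXCL17, a mucosal chemokine, stood at 263, 204 and 124 CPM against 3.95, 5.34 and 10.0 CPM (log2 5.01, SE 0.52, adjusted p = 0.00586). AKR1C1, an aldo-keto reductase that inactivates progesterone and has close paralogs, rose by 3.54 (SE 0.47, adjusted p = 0.0253), and SAA1, which has the near-identical paralog SAA2, by 4.53 (SE 0.65, adjusted p = 0.0408). SAA1 stood at 785, 281 and 838 CPM against 31.0, 9.80 and 40.2 CPM, and each of the 4 genes was above all normal libraries in 3 of 3 adenoma libraries. The genes lie on chromosome 3 (RARRES1, 158696892 to 158732696), 19 (CXCL17, 42428288 to 42443048), 10 (AKR1C1, 4963253 to 4983283) and 11 (SAA1, 18266174 to 18269977). SAA1, SLPI and LCN2 lead the smaller of the 2 clusters in this class, which held 116 of 141 such cells of NFPA 5, 31 of 135 of GH adenoma 4 and 21 of 111 of CD adenoma 3, but 6 of 444, 5 of 108 and 7 of 94 in the normal glands. PRL, from hormone cells, stood at 64690, 1255 and 3.88 CPM in this class in the adenomas and at 9222, 37200 and 8740 CPM in the normal glands. Mitochondrial transcripts had 13 of 13 below 0 in the adenomas (median log2 -1.573), nuclear oxidative phosphorylation 17 of 18 (-0.304) and ribosomal protein genes 17 of 18 (-0.29), with no test. In the larger cluster alone 0 genes were called by edgeR, with 103 at an unadjusted p under 0.05. With the replicate block, which compares the groups within 2 donor pairs alone, 60 genes were called (45 higher, 15 lower). Normal gland 2 and NFPA 5 add nothing to that difference. With DESeq2 73 genes were called. The count was 0 without normal gland 2 or 3, 8 without GH adenoma 4, 9 without NFPA 5, 14 without CD adenoma 3 and 15 without normal gland 4.

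**Figure D3:**
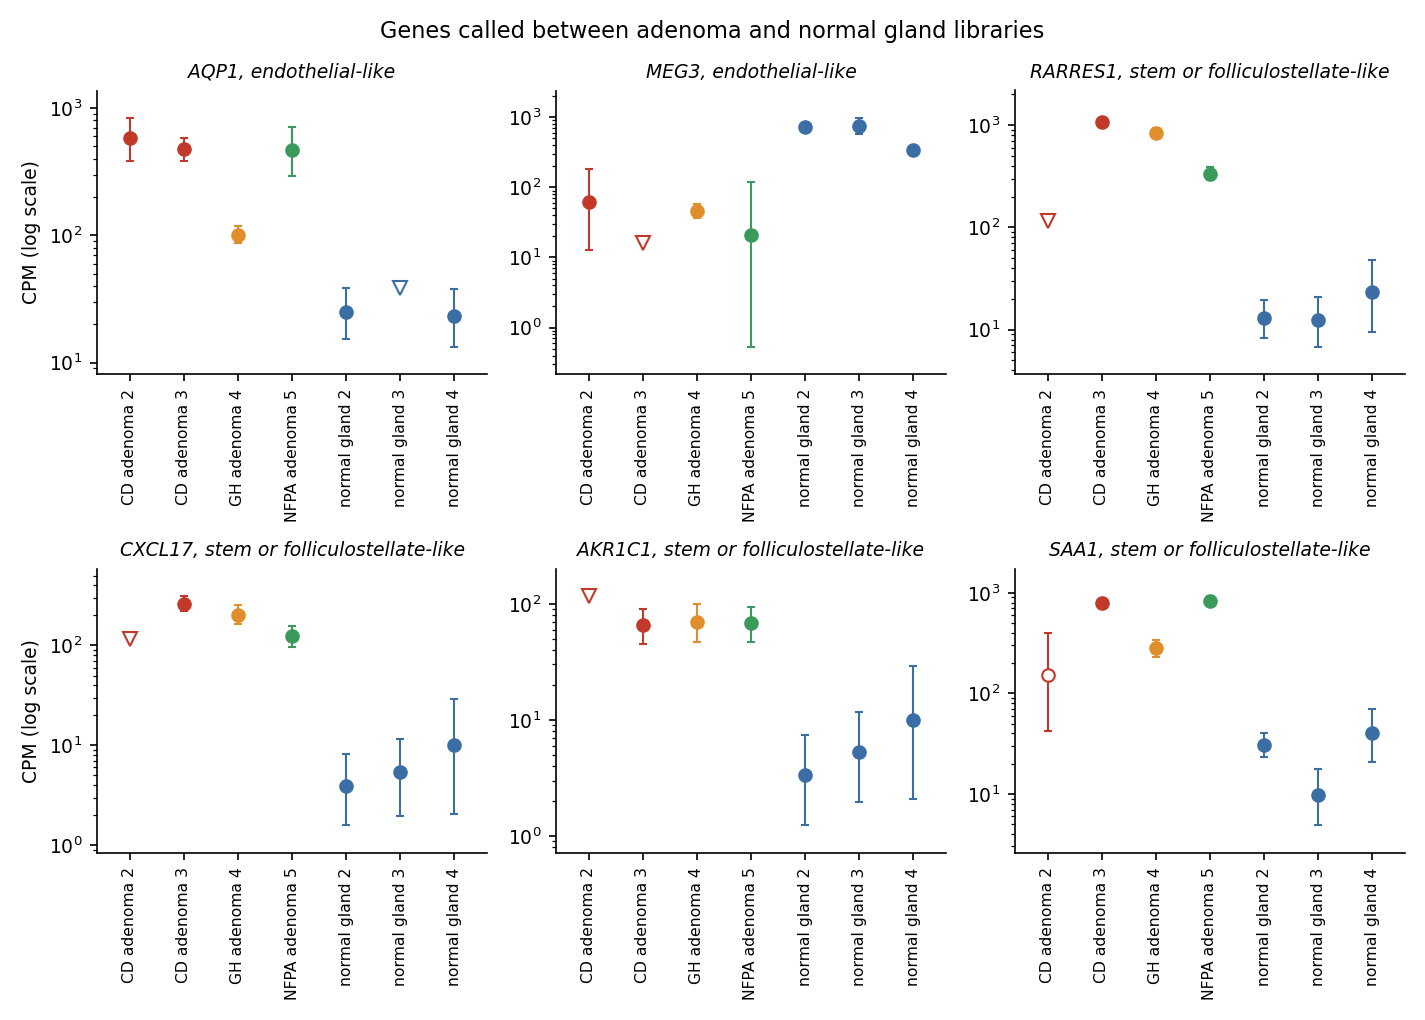
Expression of the 6 genes called in endothelial-like cells (AQP1, MEG3) and in stem or folliculostellate-like cells (RARRES1, CXCL17, AKR1C1, SAA1), 1 point per library, in counts-per-million (CPM, log scale) with exact Poisson 95% intervals; open triangles mark a count of 0 drawn at the floor of 3 counts. Among libraries with at least 20 cells the adenomas lie above every normal gland for AQP1 and for the 4 stem-like genes, and below for MEG3.

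In fibroblast-like, macrophage-like and T-cell-like cells no gene passed with edgeR. Of 4006 genes in fibroblast-like cells 0 were called (106 at an unadjusted p under 0.05), with DESeq2 6, with the replicate block 2 and without GH adenoma 4 4. FN1, which encodes fibronectin and was chosen after its values were seen, stood at 562, 1242, 407 and 1096 CPM in the 4 adenomas against 58.6, 41.5 and 94.0 CPM (log2 3.43, SE 0.55, adjusted p = 0.101 with edgeR, 4 of 4 above all normal libraries). Of 5886 genes in macrophage- or monocyte-like cells 0 were called (67 at an unadjusted p under 0.05), with DESeq2 1, with the replicate block 6, and without CD adenoma 2 or normal gland 4 2. HBB, a red-cell gene also chosen after its values were seen, stood there at 209, 7.66, 3.45 and 7.57 CPM against 1657, 1324 and 956 CPM (adjusted p = 0.137 with edgeR). Of 5374 genes in T-cell-like cells 0 were called (22 at an unadjusted p under 0.05), with DESeq2 0, with the replicate block 12, without normal gland 3 3 and without normal gland 4 2. RNA of hormone cells lay in these classes too: in fibroblast-like cells POMC stood at 77370 CPM in CD adenoma 2, and PRL at 7279, 2035 and 2514 CPM in normal glands 2, 3 and 4. Mitochondrial transcripts had 11 of 13 below 0 in the adenomas in fibroblast-like cells, and 13 of 13 in macrophage- or monocyte-like and in T-cell-like cells. Fibroblast-like cells also met all 5 pericyte markers. NK-cell-like cells were too few in the libraries for a test.

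GH adenoma and NFPA, with 1 library each, were set against the same cell class of normal gland with no test. Somatotroph-like cells were 4.30% of GH adenoma 4, below all 3 normal glands and 5.63 points below the gland of the same donor. Of these 172 cells 110 lie in a cluster that holds 915, 1694 and 138 cells of normal glands 2, 3 and 4. The other 62 lie in a cluster that holds 1028, 77 and 165 cells of those glands. Whether they are adenoma cells or normal somatotrophs of the same piece of tissue was not tested. In the 172 cells GH2, the placental paralog of growth hormone, stood at 1448 CPM against 153, 117 and 407 CPM in normal glands 2, 3 and 4, 6.42-fold over their mean. GH1 (chromosome 17, 63917200 to 63918838) stood at 51990 CPM against 58600, 143000 and 25300 CPM, a ratio of 0.687 to their mean. Against normal gland 4 alone, from the same donor, the direction of GH1 turned: it was 2.05-fold higher there, and GH2 3.56-fold. The genes GH1 and GH2 are near-identical, so reads of one can be counted for the other. POU1F1, the factor of the somatotroph and lactotroph lineage, stood at 404 CPM, a ratio of 0.940. ABI3BP was 6.29-fold higher, RASGEF1B 5.40-fold, CCSER1 4.85-fold, NCALD 4.62-fold, COL4A3 4.59-fold, SLC25A27 4.57-fold, NRXN3 4.44-fold, SOX5 4.14-fold and KLF6 4.12-fold. PNMT was 4.55-fold lower, POMC 4.41-fold, HYI 3.56-fold, TSPO 3.48-fold, ERCC1 3.45-fold, ACOT7 3.23-fold, C1QTNF4 3.15-fold, PLP2 3.13-fold and MSX1 3.06-fold, and HBB 85.5-fold on 1 count. The folds depended on the clusters. When all cells were clustered and named anew with doublets kept, the class held 337 cells of GH adenoma 4, none of them a called doublet and 110 of them among the 172. The GH1 ratio then became 0.263 and the GH2 fold 3.8, and all 10 of 10 higher folds and 7 of the 9 lower ones on more than 3 counts changed by over 1.5 times. In cells thinned to 1000 UMIs 3 and 6 did, none of them in direction. Against normal gland 4 alone, added after seeing the data, the 10 higher folds ran from 2.77 to 6.18 and the 9 lower ones from 1.08 (POMC) to 4.25. Ribosomal protein genes had 17 of 18 members below 0 (median log2 -0.58, percentile 0.03 of random lists), mitochondrial transcripts 9 of 13 (-0.62, percentile 0.19) and nuclear oxidative phosphorylation 14 of 18 (-0.46, percentile 0.31).

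In 7140 gonadotroph-like cells of NFPA 5 the gonadotropin genes were low to moderate beside normal gland. The class joins 2 clusters: 6955 of these cells lie in a cluster with no cell of another library, and 185 in the cluster that holds the 374, 338 and 38 gonadotroph-like cells of normal glands 2, 3 and 4. CGA stood at 2943 CPM against 19780, 12670 and 15170 CPM, 5.39-fold lower than their mean. LHB (chromosome 19, 49015980 to 49017091) stood at 2345 CPM against 5926, 908 and 9776 CPM, and FSHB (chromosome 11, 30231016 to 30235261) at 533 CPM against 353, 700 and 1124 CPM. NR5A1, the factor of the gonadotroph lineage, stood at 45.8 CPM against 72.5, 25.9 and 5.54 CPM, a ratio of 1.32 that became 0.942 in cells thinned to 1000 UMIs and 0.505 with at most 10% mitochondrial UMIs. CCND1 was 3.46-fold higher. S100B was 228-fold higher, CCDC80 95.6-fold, ZG16B 62.5-fold, IL13RA2 53.2-fold, SLC10A4 47.2-fold, A2M 45.7-fold and SGK1 44.8-fold. Of these 7 folds 3 changed by over 1.5 times in cells thinned to 1000 UMIs (the 7 then ran from 29.5 to 153) and 4 with at most 10% mitochondrial UMIs (58.6 to 6147), none in direction. VSNL1 was 557-fold higher against 1 count (pooled interval from 94.5), CDH8 506-fold against 1 count (from 85.9) and SPOCK3 385-fold against 2 counts (from 101). GH1 was at least 160400-fold lower, DLK1 at least 6426-fold, POU1F1 at least 1060-fold and PRL 2792-fold, and these genes of other lineages took 33200 CPM (GH1) and 94300 CPM (PRL) in the gonadotroph-like cells of normal gland 3. PCK1, KCNJ6 and ARHGAP36 were at least 789-fold, 650-fold and 595-fold lower, SCGB2A1 438-fold, PPP1R27 947-fold on 3 counts and PLAGL1 814-fold on 2 counts. All 12 of 12 G1 cyclin genes lay above 0 (median log2 1.39, percentile 100 of random lists) and 18 of 19 proliferation genes (0.59, percentile 97.3). Hormone processing genes had 11 of 17 above 0 (1.06, percentile 99.3), lineage factors 12 of 19 below 0 (-1.29, percentile 0) and antigen presentation genes 13 of 17 below 0 (-1.05, percentile 0.02). Signs of RNA quality and of other cells moved as far: mitochondrial transcripts had 13 of 13 below 0 (-1.99, percentile 0), ribosomal protein genes 16 of 18 (-0.446, percentile 0.01), the other hormones 6 of 6 (-3.84, percentile 0) and blood and vessel markers 8 of 10 (-1.57, percentile 0.01). Immediate early genes had 12 of 19 above 0 (0.924, percentile 98.4), the unfolded protein response 12 of 18 below 0 (-0.249, percentile 0.58) and cell cycle inhibitors 11 of 18 below 0 (-0.595, percentile 0.08).

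**Figure D4:**
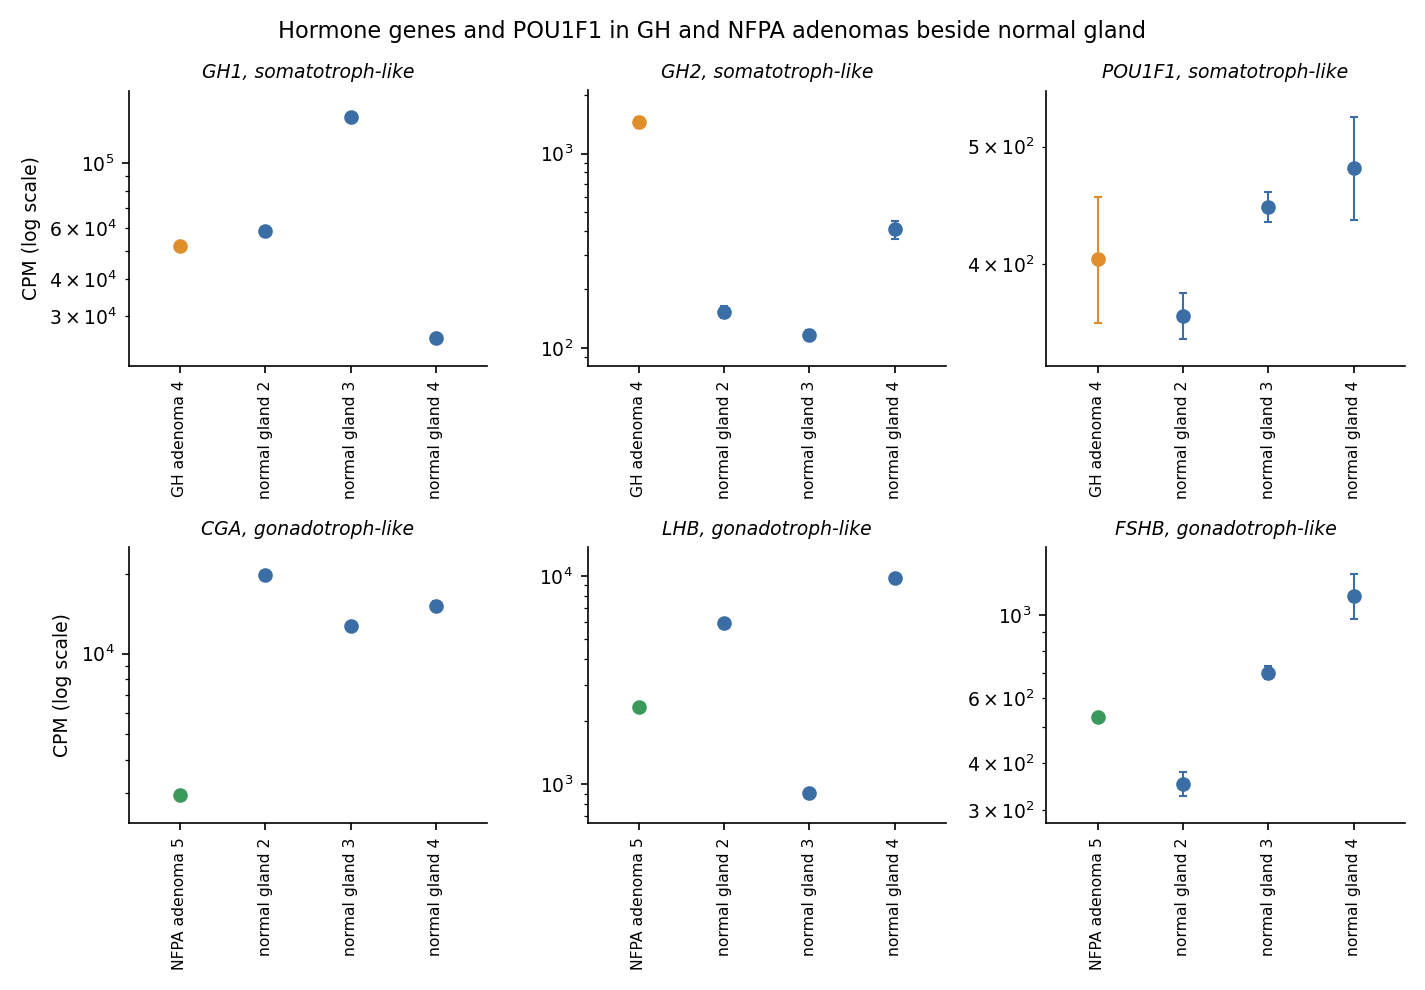
Expression of GH1, GH2 and POU1F1 in somatotroph-like cells of GH adenoma 4 and the normal glands, and of CGA, LHB and FSHB in gonadotroph-like cells of NFPA 5 and the normal glands, 1 point per library, in counts-per-million (CPM, log scale) with exact Poisson 95% intervals. GH2 stands at 1448 CPM in GH adenoma 4 above all 3 normal glands, and CGA at 2943 CPM in NFPA 5 below all 3.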

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

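The tests of the mix of stem-like clusters and of the source of MEG3, and the count of splits that part the donor pairs, were chosen after the results were seen, and the tests of free RNA, depth and other splits before.

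Among the 4 adenoma libraries, 19 classes of cells were looked at for a library far from the other 3, and chance alone marks about 1 in 20 such groups. Corticotroph-like cells made up 91.1% of CD adenoma 2, against at most 2.75% of the other adenomas. Gonadotroph-like cells made up 83.5% of NFPA 5, against at most 5.69%, but 0.199% at resolution 0.5, where the large NFPA cluster stayed unnamed. Endothelial-like cells made up 17.4% of GH adenoma 4, against at most 1.93%, but they were 10.95% of the normal gland of the same donor and 8.13% of normal gland 2. Fibroblast-like cells, whose cluster met all 5 pericyte markers too, made up 29.8% of GH adenoma 4, against at most 3.08% and 12.45% of the gland of the same donor; at resolution 2 18.5% were fibroblast-like and 11.5% pericyte-like. NK-cell-like cells made up 2.34% of CD adenoma 3, against at most 0.0584%, but at resolution 2 they also made up 2.25% of GH adenoma 4. Erythroid-like cells made up 0.126% of CD adenoma 2 (6 cells), against 0 in the others.

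The library of CD adenoma plus normal gland, which entered no comparison, stood apart in 3 values. CCND1, the cyclin that opens the G1 phase, stood at 2811 CPM in its corticotroph-like cells against 182 CPM in normal gland 3. RPS24, a ribosomal protein gene with processed pseudogenes, stood at 82640 CPM there against 2562 CPM. Of its barcodes 61.0% had most of their UMIs from haemoglobin genes.

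In corticotroph-like cells single genes such as PCSK1, KLK12 and MT1X stood apart in both CD adenomas from normal gland 3, while 0 genes passed edgeR. Free RNA of other hormones, or doublets, would shrink the differences once cells with over 1% of another hormone were left out. The median ratio of log2 differences over 184 of the first 200 genes by p was 1.008, with 183 in the same direction. This cannot decide it, since the limit left 4296 of 4350 such cells in CD adenoma 2 and 83 of 108 in normal gland 3. The genes were also picked by p from the same fit. PRL under the limit stayed in, at 1246 CPM in CD adenoma 3 and 992 CPM in normal gland 3, so free RNA and doublets stay open. In the cells kept, PCSK1 still stood at 97.0 and 320 CPM against 12.9 CPM. CGA in CD adenoma 3 went from 503 to 25.0 CPM, so the CGA there may come from other endocrine cells, although the limit itself reads CGA. Depth per cell (medians of 15640, 3342 and 8298 UMIs in CD adenoma 3, CD adenoma 2 and normal gland 3) remains open: after thinning to 1000 UMIs the median ratio was 1.002, but 49 of the 200 genes could be measured. A disease effect, a donor effect and the small number of normal cells stay untested, with 1 normal library in the fit. Whether the corticotroph-like cells of CD adenoma 3 are adenoma cells was not tested either. Normal gland 3 also stood apart from the other glands, in cells with no other hormone over 1%. MT1X stood at 3870 CPM there, but at 417 CPM (180 to 822) in 7 cells of normal gland 2. In 2 cells of normal gland 4 it stood at 929 CPM (531 to 1509), and in CD adenomas 2 and 3 at 298 and 237 CPM. PCSK1 stood at 12.9 CPM in normal gland 3 and 174 CPM (3 counts, 35.9 to 509) in normal gland 4. Normal gland 2 had 0 counts of it (up to 192 CPM).

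RARRES1, CXCL17, AKR1C1 and SAA1 were higher in stem or folliculostellate-like cells of the adenoma libraries. Whether a different mix of the 2 clusters of this class explains it stays open: in the larger cluster alone the median log2 fold of the 4 genes was 0.8509, against 4.62 in the class, but SAA1 leads the smaller cluster beside SLPI, LCN2 and KRT7, so the way the cells were divided fixed part of that drop. In clusters found without the 4 genes and their close relatives, the largest group of the class kept a median of 2.26, with RARRES1 at 3.533 and AKR1C1 at -0.4233 on 5 counts in the adenoma libraries, which decides neither way. The other group held 115 cells of NFPA 5, 10 of CD adenoma 3 and 7 of GH adenoma 4 but 1 of the normal glands, and what these cells are was not tested. Of 10 splits of the 6 libraries into groups of 3, 1 gave as many genes, the real one with 4, and the highest other gave 0; the splits are too few for a share under 0.05.

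AQP1 was higher and MEG3 lower in endothelial-like cells of the adenoma libraries. Chance cannot be excluded over all splits, since 3 of 35 called as many genes as the real 2. The highest other, the real split with GH adenoma 4 set among the normal glands, called 72. It parts GH adenoma 4 from the other adenomas and also keeps both libraries of donor 4 on the same side, so these cannot be told apart. Without GH adenoma 4 37 genes were called. Of the 8 splits that part all 3 donor pairs the real one called 2 genes and the highest other 0, too few splits for a share under 0.05, and with the replicate block 49 genes were called. MEG3 could come from free RNA of hormone cells, where it is abundant: its ratio to PRL in endothelial-like over T-cell-like cells was 2.868 and 4.621 in normal glands 2 and 4 but 1.256 in normal gland 3, so this source and expression by the vessels cannot be told apart. A difference between vessels of adenoma and of gland stays untested.

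In fibroblast-like, macrophage-like and T-cell-like cells the real split called 0 genes, so all 35 of 35 splits had to give as many, and the count decides nothing about chance. The highest other splits called 54, 241 and 1049 genes, each with both libraries of donor 4 on the same side, which points to a structure of the samples other than the groups. None of the 8 splits that part all 3 donor pairs called a gene in these classes; with the replicate block 2, 6 and 12 genes were called.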

How the results depend on the processing

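The fit without a minimum of cells, removal of the top doublet scores, the larger stem-like cluster alone, the clusters led by PRL and the GH folds against the gland of the same donor were chosen after seeing the data, and the other alternatives before. Over 880 alternative values, 147 answers to a comparison and 500 values of single genes kept their direction and side of the threshold, while 109 single genes no longer passed, 11 newly passed, 33 moved and 8 turned; of the answers 66 moved and 6 turned. A count of genes or lists moved when it changed by over 1.5 times or to or from 0, and a fold with no test when its value left the 95% counting interval. No paired analysis was possible for corticotroph-like cells with the minimum of 20 cells, because 1 normal gland met it, and neither could a replicate be left out there. Depth limits the normal side, where 9, 108 and 2 corticotroph-like cells gave 41160, 1009452 and 17220 UMIs. Except where a cause is given, it was not tested.

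For corticotroph-like cells, edgeR called 0 genes, DESeq2 19, edgeR with no filter 107, and edgeR on thinned cells 21, from fewer genes tested. POMC, at -0.02 on the log2 scale, became 0.098 with no filter, 0.0103 at resolution 0.5 and 0.178 thinned; TBX19 became 0.095, 0.0086 and 0.206, and 0.0541 at 10% mitochondrial UMIs; MCL1, at 0.20, became -0.76 thinned. Without the minimum of cells, 28 genes became 2 with DESeq2, 75 with no filter, 17 with the replicate block, 17 with no other hormone over 1% and 3 thinned, and 0 to 281 leaving out 1 library. For all cells 0 became 41 with DESeq2 and 0 to 388 leaving out 1 library.

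For endothelial-like cells 2 genes became 19 with DESeq2, 52 with no filter, 49 with the replicate block, 0 at 10% mitochondrial UMIs, 0 with doublets kept, 0 with top doublet scores removed, and 0 to 37 leaving out 1 library. For fibroblast-like cells 0 became 6 with DESeq2, 38 with no filter, 2 with the replicate block and 0 to 4 leaving out 1 library. For macrophage-like cells 0 became 1 with DESeq2, 9 with no filter, 6 with the replicate block, 3 at 10% mitochondrial UMIs, 2 with doublets kept and 0 to 2 leaving out 1 library. For T-cell-like cells 0 became 6 with no filter, 12 with the replicate block, 4 at 10% mitochondrial UMIs and 0 to 3 leaving out 1 library. For stem-like cells 4 became 73 with DESeq2, 327 with no filter, 60 with the replicate block, 7 at 10% mitochondrial UMIs, 0 in the larger cluster and 0 to 15 leaving out 1 library. RARRES1, CXCL17, AKR1C1, SAA1, AQP1 and MEG3 kept their direction in every alternative run on the whole class.

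The 9 lists called with the preset correlation became 0 with an estimated correlation and 0 with fry, which did not find a list raised 2-fold in simulated data, and so did the partly different 9 called without the minimum of cells, of which 5 were the same lists. The latter became 4 with the replicate block and 0 to 11 leaving out 1 library. The GH1 ratio of GH adenoma became 0.695 thinned, 0.614 at 10% mitochondrial UMIs and 0.263 with doublets kept, where the class was clustered anew and held no called doublet, so the new clusters changed it. Against the normal gland of the same donor alone the GH1 fold turned to 2.055. In NFPA the CGA ratio became 0.154 and the LHB ratio 0.388 thinned, and the NR5A1 ratio became 0.942 thinned and 0.505 at 10% mitochondrial UMIs. Leaving out 1 library, the difference in share ran from -5.35 to 0.34 percentage points for gonadotroph-like cells, from -5.95 to 0.547 for macrophage-like cells and from -5.40 to 14.04 for T-cell-like cells. Within donors the gonadotroph-like share was lower in both CD adenomas, by -7.24 and -1.86 points in replicates 2 and 3. The lactotroph-like share was lower in CD adenomas wherever a cluster took that name, by 3.88 to 15.84 points and by 9.27 points with the unnamed clusters led by PRL; at resolution 2 and with doublets kept none did. The gonadotroph-like share of NFPA became 62.7% at resolution 2 and 0.199% at resolution 0.5, where its large cluster got no name. The fibroblast-like share of GH adenoma became 18.5% at resolution 2, where pericyte-like clusters took 11.5%. The corticotroph-like share of CD adenoma 2 became 53.6% at 10% mitochondrial UMIs, which left 315 of its cells. The corticotroph-like share was higher in CD adenomas under every alternative, by 1.87 to 90.3 points.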

Other observations

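The values in this part were chosen after they had been seen, and no test was planned for them.

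CRH, the hypothalamic hormone that drives corticotrophs, was counted in the corticotroph-like cells of both CD adenomas. CD adenoma 2 had 337 counts, 16.7 CPM (15 to 18.6), in 137 of 4350 such cells (3.15%, 2.65 to 3.71%), at a median of 3342 UMIs per cell. CD adenoma 3 had 31 counts, 19.9 CPM (13.5 to 28.3), in 12 of 74 cells (16.2%), at a median of 15640 UMIs. Cells of other kinds held 1 count in CD adenoma 2 (1 of 423 cells, 0.236%, median 847 UMIs) and 5 counts in CD adenoma 3 (4 of 2617 cells, 0.153%, median 4137 UMIs). In normal gland 3 it was not detected in 108 corticotroph-like cells (0 counts, floor 2.97 CPM), nor in 1045 such cells of the library of adenoma plus normal gland (floor 0.481 CPM). In CD adenoma cells with no other hormone over 1%, CRH stood at 16.7 CPM (332 counts) and 11.6 CPM (6 counts, 4.24 to 25.2). Without a minimum of cells edgeR gave CRH an adjusted p of 0.0540, so it was not called.

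MEG3, which is abundant in hormone cells of the gland, stood at 21.3 CPM (524 counts) in gonadotroph-like cells of NFPA 5 against 3268, 2448 and 1340 CPM in those of normal glands 2, 3 and 4, and 1708 and 1691 CPM in those of CD adenoma 3 and GH adenoma 4. Somatotroph-like cells of GH adenoma 4 held 4619 CPM of MEG3 against 4387, 4014 and 5488 CPM, and corticotroph-like cells of CD adenomas 2 and 3 held 1147 and 1568 CPM against 1206 CPM in normal gland 3. Over all cells NFPA 5 stood at 27.3 CPM and the normal glands at 3723, 3337 and 3740 CPM.

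In the library of CD adenoma plus normal gland, 1045 corticotroph-like cells held 237900 CPM of POMC, 290 CPM of TBX19 and 409 CPM of PMAIP1. PCSK1 stood at 198 CPM, 15.4-fold over normal gland 3. LCN1 stood at 113 CPM there, 61.1 CPM in CD adenoma 3 and 1.39 CPM in CD adenoma 2, with 0 counts in normal gland 3, and DKK4 at 16.2, 81.6 and 6.01 CPM with 0 counts in normal gland 3. PPP1R17 stood at 234 CPM there, with 852 and 242 CPM in CD adenomas 2 and 3 and 9.91 CPM in normal gland 3. In normal gland 2 it stood at 146 CPM (6 counts, 53.5 to 317), in 3 of 9 corticotroph-like cells. Normal gland 4 had 0 counts of it (up to 214 CPM). CYP3A4, a drug-metabolising enzyme, stood at 293 CPM in the library of adenoma plus normal gland and at 125 CPM in CD adenoma 2. It stood at 1.28 CPM in CD adenoma 3 (2 counts), with 0 counts in normal gland 3. HBB took 8539 CPM of the 1045 cells of the library of adenoma plus normal gland, 953 CPM in CD adenoma 2 and 122 CPM in normal gland 3.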
